A study of Mus musculus with 6 samples.

How the data were processed

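Messenger RNA was measured on 6 Illumina mouse expression arrays with 1 colour, 2 for each of 3 peptide ligands (MCC, gp250 and Hb) presented by plate-bound I-Ek dimers. Per the labels, thymocytes were stimulated for 7 h, total RNA was isolated with a Qiagen kit and biotinylated cRNA was made with the Ambion kit for Illumina arrays. Groups and replicate numbers were taken from the sample titles. The scanner software and its version are not given in the sources used here.

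Per the file headers, the authors deposited for each probe and array a non-normalized intensity and a detection p-value. The intensity goes below 0 on every array and is near 0 where the detection p-value is 0.5, so a background had been subtracted before it was deposited. The detection p-value, which the deposited table gives in steps of 1 in 798, never rose with the signal of its own array. The authors' processed table holds the same intensity on a linear scale, multiplied by 1 factor per array, between 0.825 and 1.13, so that every array has a mean of 505. Its medians ran from 17.9 to 21.6. It is not centred on genes, and it served as an alternative. Mean intensity per array was 582 to 613 for MCC, 445 to 482 for gp250 and 470 to 488 for Hb.

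Of 25697 probes, 23978 had 1 gene symbol in the platform annotation, 0 had several and 1719 had none here. Of the probes, 23962 were matched by Entrez number to the RefSeq gene table of the GRCm38.p6 assembly, which was used for names only. No genome build is named in the sources used here, so no coordinates are given. Some members of the gene lists had no named probe and were not analysed here.

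All computation was done in R 4.3.3 with limma 3.58.1. Intensities were background-corrected by normexp with control parameters inferred from the detection p-values, an offset of 16 was added, and the arrays were quantile-normalized and put on the log2 scale (neqc). The normexp step thus acted on signals from which a background had already been subtracted, and the offset pulls the fold changes of dim probes towards 0. A probe was tested if its detection p was under 0.05 on at least 2 of the 6 arrays, which left 11942 probes, 11234 of them with a symbol, for 8253 genes. For 2137 genes more than 1 probe was tested. Gene lists and named genes use the probe with the highest mean signal. Other probes of a gene could change by another amount, and the text gives them for some genes only. A linear model with 1 mean per ligand was fitted to all 6 arrays, which leaves 3 residual degrees of freedom, so the spread is shared between the ligands. Moderated tests (eBayes, no trend) were adjusted by Benjamini-Hochberg within each of 3 comparisons, and an adjusted p under 0.05 was called. A probe was apart in gp250 alone, or graded, only if gp250 differed from both other ligands by this test. Errors are standard errors of log2 fold changes from limma unless SD is written, and intervals are 95% intervals from the same model.

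A gene below background on both arrays of a ligand has only a bound there. Its fold is written "at least", and is the mean normalized signal of the brighter ligand against, per array of the dimmer ligand, the higher of the lowest detected signal and the probe's own.

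The 22 gene lists, for selection, signalling, survival, metabolism and possible other cell types, were fixed before the data were examined, as were the tests, the named genes and the alternatives, except where the text says otherwise. Each list was tested against all other genes with camera at an inter-gene correlation of 0.01, adjusted over the 22 lists. The same test with the correlation estimated per list, and fry, were alternatives. The rule for named genes took, in each comparison, the 8 largest rises and 8 largest falls among probes with 1 symbol, an adjusted p under 0.05, detection on both arrays of the higher ligand and no overlap between the arrays of the 2 ligands. It added up to 2 called members of each list, or up to 4 where camera called the list. Always named, where analysed here, were Nr4a1, Egr1, Egr2, Cd69, Cd5, Bcl2l11, Rag1, Rag2 and Scn4b.

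The steps after background correction were tested on simulated data with the spread of these arrays. Values were drawn and changed on the normalized log2 scale. The pull of background correction and offset on dim probes was therefore not simulated, and changes of all 4 sizes shared 1 adjustment. Of 50 probes changed at each of 4 sizes between gp250 and Hb, 12% were recovered for changes of 25%, 60% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, and 7 of 11742 unchanged probes were called. The list test, on genes drawn independently, called 3 of 3 lists shifted by 0.5 (log2) and 1 of 19 others. The covariance that the shared Hb arrays give to the MCC and gp250 responses was taken from 100 simulated sets of unchanged groups.

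Alternatives were no background correction, an offset of 50, scaling to a common median without the quantile step, no scaling between arrays (chosen after the data were seen), the authors' processed values, no filter and a stricter filter on dim probes. Others were another variance model, fits to only the 4 arrays compared, the replicate number as a block, leaving out each array in turn, the mean of a gene's probes for the lists, and other thresholds. A count was taken as unmoved within 1.5 times. A gene's direction was judged only where its value passed the test, and the correlation of responses against its standard deviation over single arrays. No slide or scan date is given in the sources used here.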

Results

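The series measured messenger RNA in thymocytes taken before selection, at the stage that carries both CD4 and CD8. They came from Rag1-deficient mice with the AND T cell receptor, which recognises a moth cytochrome c peptide (MCC) on the class II molecule I-Ek. The H-2d background of these mice does not select the AND receptor, so the cells wait at this stage. Thymocytes were held for 7 h on plates coated with I-Ek dimers that carried 1 of 3 peptides. Per the labels, MCC gave negative selection signals, gp250 gave positive selection signals and Hb was non-selecting. Each ligand had 2 arrays, 6 in all, and every array read 25697 probes in 1 colour. The mean deposited signal was 582 to 613 with MCC, 445 to 482 with gp250 and 470 to 488 with Hb, and 10519 to 11603 probes per array were detected above background. Within each ligand the replicates correlated with r = 0.994 over the 11942 tested probes, and the number of arrays limits the precision. The labels do not say that the arrays came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The Rag1 probe was detected on all 6 arrays of these Rag1-deficient cells. Where it lies relative to the disrupted part of the gene is not given in the sources used here, so it checks nothing about the genotype.

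The comparison of MCC with Hb asks what a negative-selecting ligand changes against a ligand that selects nothing. MCC changed a large part of the measured transcripts, in both directions. Egr2, a transcription factor induced by T cell receptor signals, rose 55.0-fold (log2 fold change 5.78 ± 0.09, SE, n = 2 arrays per ligand). Cd69, an early activation marker, rose 19.4-fold (4.28 ± 0.11), and Cd5, a surface receptor that dampens receptor signals, rose 29.8-fold (4.90 ± 0.14). Rag1, part of the enzyme that recombines receptor gene segments, fell by 3.66 ± 0.11 on the log2 scale, and Dntt, which adds nucleotides at the joins, fell by 4.62 ± 0.18. Cd4, the coreceptor for class II molecules, was below background on both MCC arrays and at least 16.9-fold lower than with Hb.

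In total, 6545 of the 11942 probes passed an adjusted p of 0.05 in limma (54.8%), of which 3176 rose and 3369 fell. A change of at least 2-fold was measured for 2092 of these probes, 1067 up and 1025 down, and of at least 16-fold for 51 probes, 32 up and 19 down. The passing probes name 4789 genes. Changes are relative to the signals of the whole array: without scaling between arrays, a setting added after the data were seen, the median probe was 0.22 (log2) higher with MCC, and of 6691 passing probes 4674 rose and 2017 fell. The largest fitted rise belonged to Cldn10, a tight junction claudin, at 106-fold (log2 6.73 ± 0.10). Xcl1, a chemokine made by lymphocytes, followed at 86.6-fold (6.44 ± 0.22), although its probe was detected on only 1 of the 2 Hb arrays. The adaptor gene Sh3bp2 rose 51.1-fold, the epoxide hydrolase gene Ephx1 49.7-fold and Itm2a, a membrane protein gene known to be induced during thymocyte selection, 40.9-fold. Akr1c18, a hydroxysteroid dehydrogenase gene, and Cd160, a receptor gene of lymphocytes, were below background on both Hb arrays and at least 33.5-fold and 38.5-fold higher with MCC. Such bounds do not fix their place in this order. The steepest falls included another claudin gene, Cldn4 (24.6-fold lower), Plxdc1 (23.5-fold), the meiotic recombination gene Spo11 (21.3-fold), Endou (19.3-fold) and the cytokine signal suppressor Socs3 (19.3-fold). Dimmer probes of Plxdc1 (log2 -3.26) and Spo11 (log2 -1.33) changed less. Insl5, which encodes an insulin-like peptide, was at least 15.6-fold lower. Adjusted p-values of these 16 largest changes ran from 2.33e-06 to 7e-06.

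Genes known to respond early to receptor signals rose together. Of the 19 tested immediate-early and EGR/NR4A genes, 15 rose and 0 fell (camera adjusted p = 2.52e-06; adjusted p = 0.158 with an estimated correlation). Beside Egr2, Egr1 rose 22.8-fold (log2 4.51 ± 0.18) and the transcription factor gene Irf4 10.5-fold, with Irf4 detected on 1 of the 2 Hb arrays. Nab2, a corepressor of EGR factors, was at least 10.2-fold higher. The only probe of Nr4a1 was not detected on any of the 6 arrays and was not tested. Of 22 ERK phosphatases and attenuators of receptor signals, 14 rose and 2 fell (adjusted p = 0.00159; adjusted p = 0.241 with an estimated correlation). Cd6, a relative of Cd5, rose 7.84-fold, and the phosphatase gene Dusp4 was at least 5.62-fold higher on its brightest probe. A dimmer Dusp4 probe changed less (fitted log2 1.26, beside 2.89). Cd5 had the largest rise of this list, while Socs3 and Dgka, a diacylglycerol kinase gene (log2 -1.05), fell. Among 15 cytokines and costimulatory receptors, 11 rose and 2 fell (adjusted p = 0.00073; adjusted p = 0.18 with an estimated correlation). They included Cd274, which encodes the PD-1 ligand PD-L1, with a log2 fold change of 4.39 ± 0.09, the costimulatory receptor gene Icos at 8.21-fold, and Tnfrsf9 (4-1BB), at least 13.5-fold higher. The inhibitory receptor genes Lag3 (log2 -1.49) and Ctla4 (-0.80) fell. Dgka, Lag3, Ctla4 and the further members given below with a log2 value alone were outside the rule for named genes and were chosen after their values were seen.

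The lists for 2 fates of thymocytes moved in the same comparison. Of 14 genes tied to negative selection, 10 rose and 3 fell (adjusted p = 0.0047; adjusted p = 0.18 with an estimated correlation). Ikzf2, which encodes the transcription factor Helios, rose 8.95-fold (log2 3.16 ± 0.25) and the stress gene Gadd45g rose 5.00-fold. The members that fell were the death receptor gene Fas (log2 -1.91), Lag3 and Bbc3, which encodes the death-promoting protein PUMA (-1.18). Bcl2l11, which encodes the death-promoting protein BIM, did not pass the test (log2 -0.03 ± 0.11, adjusted p = 0.853), and its 3 tested probes lay between -0.04 and 0.48. Of 18 genes of maturation after positive selection, 12 rose and 6 fell (adjusted p = 0.0047; adjusted p = 0.241 with an estimated correlation). The call of this list was also lost without scaling between arrays (adjusted p = 0.0685), although its median log2 change was not smaller there (2.18, against 1.83 with the quantile step). Itm2a, Cd5, Cd69 and Bcl2 led the rises. Bcl2, a survival gene, rose 18.5-fold on its brightest probe, detected on 1 of the 2 Hb arrays, and all 6 of its probes rose, with fitted log2 changes of 2.58 to 4.40. The probes other than the brightest were detected on the MCC arrays alone, so their fitted changes are against background. The members that fell were Themis, the migration regulator Klf2 (log2 -1.96), the integrin gene Itgb7 (-1.92), the cytokine signal suppressor Socs1 (-0.78), and the receptor genes Il7r and Ccr7, both below background with MCC. Of 13 genes of the stage before selection, 11 fell and 2 rose (adjusted p = 0.000147; adjusted p = 0.18 with an estimated correlation). Arpp21 fell by 3.94 ± 0.11 on the log2 scale, and Rag2, the partner of Rag1, was at least 8.64-fold lower. The transcription factor genes Lef1 (log2 1.82) and Bcl6 (0.32) rose.

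Genes of growth and metabolism rose as well. Ribosome biogenesis had 16 of 17 tested members up and 0 down (adjusted p = 8.39e-09; adjusted p = 0.146 with an estimated correlation). The processing factor gene Rrp12 rose 21.9-fold, Rcl1 6.57-fold and Odc1, the first enzyme of polyamine synthesis, 5.38-fold, while Srm, the spermidine synthase gene, was at least 31.6-fold higher on its brightest probe. The 3 tested Srm probes had fitted log2 changes of 3.93 to 5.06. Beside ribosome factors, the list thus holds the polyamine synthesis genes Odc1 and Srm, and also Cad, a gene of pyrimidine synthesis. In glycolysis 9 of 14 rose and 1 fell (adjusted p = 0.00464; adjusted p = 0.279 with an estimated correlation). Aldoa (aldolase) rose 4.47-fold, Pfkp (phosphofructokinase) 3.93-fold and Ldha (lactate dehydrogenase) 2.48-fold, and the hexokinase gene Hk2 was at least 8.87-fold higher, while Pfkm, another phosphofructokinase gene, fell (log2 -0.91). In cholesterol synthesis 10 of 15 rose and 1 fell (adjusted p = 0.00386; adjusted p = 0.18 with an estimated correlation), led by the demethylase gene Cyp51 at 5.91-fold and the cyclase gene Lss at 3.81-fold. Sqle (2.24-fold) and Srebf2 (2.24-fold), the latter a regulator of the pathway, rose less, and Sc5d, a desaturase gene of the pathway, fell (log2 -0.89). In heat shock and the unfolded protein response 12 of 16 rose and 1 fell (adjusted p = 0.00138; adjusted p = 0.18 with an estimated correlation). Asns, which encodes asparagine synthetase, rose 10.8-fold and the chaperone gene Pdia4 4.30-fold. Hspa5 (BiP) and Chac1 were at least 2.73-fold and 1.52-fold higher, and the heat shock gene Hspa1a fell (log2 -0.73).

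**Figure D1:**
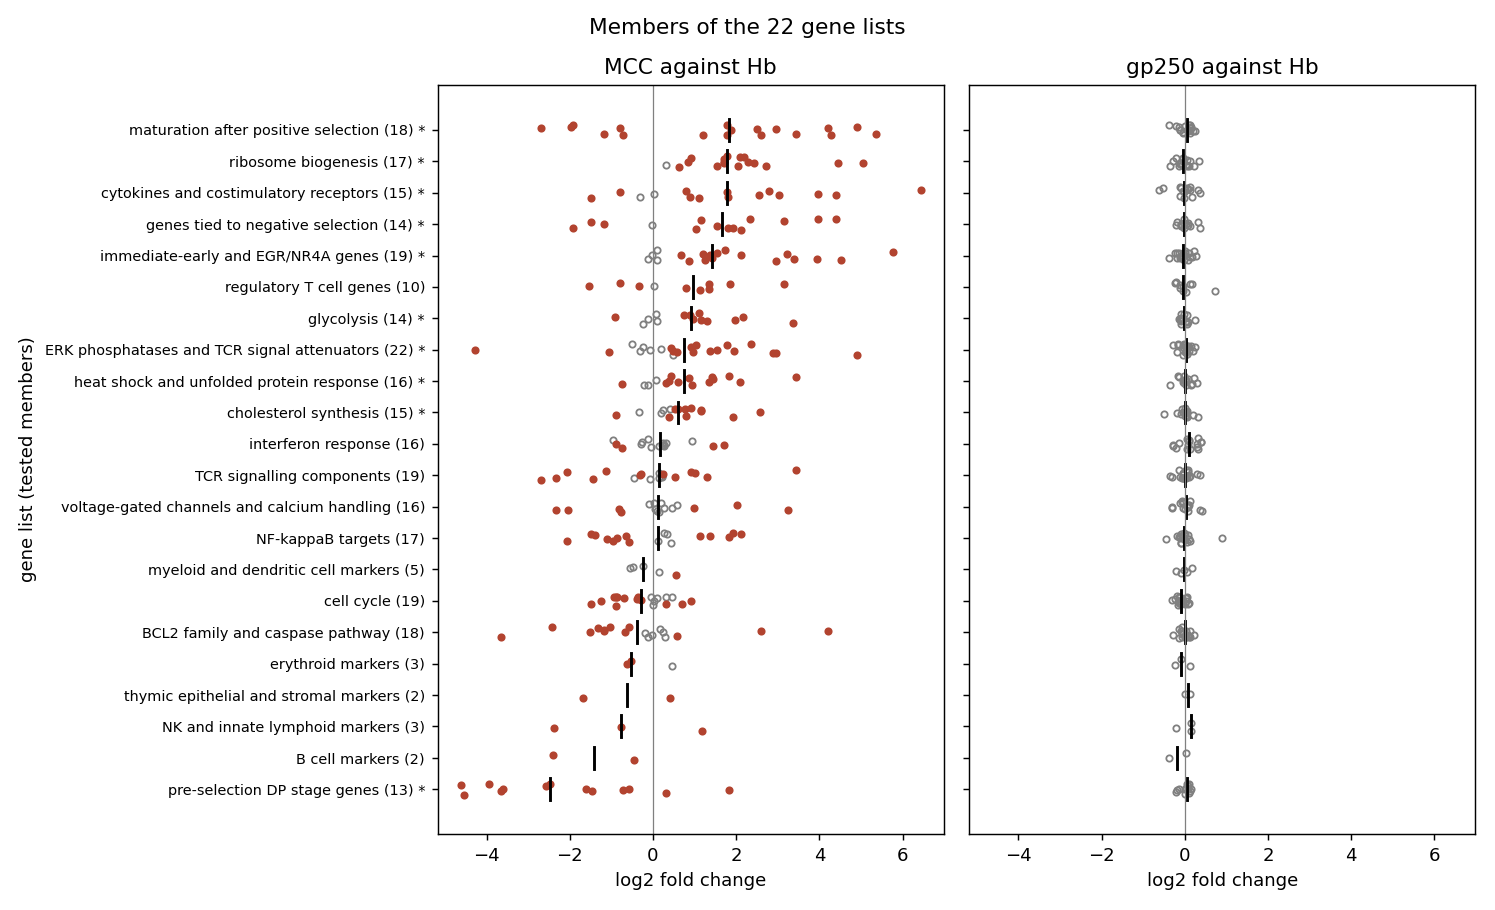
Each point is a tested member of a gene list (1 probe per gene), placed by its log2 fold change for MCC against Hb (left) and gp250 against Hb (right). Filled red points passed an adjusted p of 0.05, open points did not, black bars are list medians, numbers in parentheses count tested members and an asterisk marks the 10 lists called by camera for MCC against Hb. On the right no member passed the test.

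The other lists were not called by camera, and most held members that went both ways. In the BCL2 family and caspase pathway 3 of 18 rose and 9 fell (adjusted p = 0.193). Bcl2 rose there while its relative Bcl2l1, which encodes the survival protein BCL-XL, fell by 3.66 ± 0.09 on the log2 scale. NF-kappaB targets had 5 up and 8 down of 17 (adjusted p = 0.893), with Tnf at least 3.95-fold higher and Ltb 4.21-fold lower. Their median was 0.12 and their mean 0.03, while the test pointed down. Regulatory T cell genes had 6 up and 3 down of 10 (adjusted p = 0.193), among them Ikzf2 and Izumo1r, the latter at least 2.05-fold higher. TCR signalling components had 6 up and 7 down of 19 (adjusted p = 0.985), with a median of 0.15 and a mean of -0.14; the test pointed down, and its direction flipped under another scaling. The adhesion receptor gene Cd2 rose 10.9-fold, and Themis, needed for thymocyte selection, fell by 2.68 ± 0.08 on the log2 scale. Voltage-gated channels and calcium handling had 3 up and 4 down of 16 (adjusted p = 0.705). Orai1, the pore of the store-operated calcium channel, rose 9.52-fold, and Scn4b, a sodium channel subunit gene, was at least 3.74-fold lower. In the cell cycle list 3 of 19 rose and 10 fell (adjusted p = 0.258), with Rrm2 2.80-fold lower and the cyclin gene Ccne2 at least 1.77-fold lower. The interferon response had 2 up and 2 down of 16 (adjusted p = 0.775; its test direction flipped without scaling between arrays), with Gbp3 3.25-fold higher and Isg20 at least 2.35-fold higher.

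Markers of other cells that a thymus preparation could hold were tested where a named probe was detected, which held for 15 of 69. Of these, 3 rose and 7 fell. The myeloid and dendritic list had 1 up and 0 down of 5 (H2-Ab1, 1.46-fold), with a median of -0.24 although the test pointed up (adjusted p = 0.985), a direction that flipped under another scaling. B cell markers had 0 up and 2 down of 2 (adjusted p = 0.123), erythroid markers 0 up and 2 down of 3 (adjusted p = 0.6). Stromal markers had 1 up and 1 down of 2 (adjusted p = 0.728), and NK and innate lymphoid markers 1 up and 2 down of 3 (adjusted p = 0.581). Cd79b (5.27-fold lower), Pecam1 (3.19-fold lower), Nkg7 (2.27-fold higher) and Il18r1 (at least 3.08-fold lower) changed most. The calls of H2-Ab1, Krt8, Cd79a and Hba-a1, all under 1.5-fold, were each lost when 1 array or another was left out. Krt8 (log2 0.41) gave 0.27 without MCC replicate 1, 0.41 without Hb replicate 1 and 0.42 without Hb replicate 2. H2-Ab1 (0.55) gave 0.49 without Hb replicate 1 and 0.52 without MCC replicate 2. Hba-a1 (-0.53) gave -0.50, -0.55 and -0.39 without MCC replicate 1, MCC replicate 2 and Hb replicate 2. Cd79a, below background on both MCC arrays, had fitted values of -0.39, -0.50 and -0.29 in place of -0.45 without the same arrays.

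Counts of changed members adjusted over the list alone differed from those over all probes in 6 lists. They gave 4 in place of 2 falls for the ERK phosphatases and attenuators, 3 in place of 2 for cytokines and costimulatory receptors and 11 in place of 10 rises for cholesterol synthesis. They also gave 17 in place of 16 rises for ribosome biogenesis, 4 in place of 3 rises for the cell cycle, and 7 rises and 8 falls in place of 6 and 7 for TCR signalling. With a correlation estimated per list from these 6 arrays, 0 of the 22 lists were called, and 5 had an unadjusted p under 0.05 by that test. With fry, which asks only whether a list's own genes move one way on balance, 20 were called.

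The comparison of gp250 with Hb asks what a positive-selecting ligand changes after the same time. No change was detected at any probe. Egr1, which MCC raised 22.8-fold, differed by -0.00 ± 0.18 (log2, 95% interval -0.44 to 0.43), Cd69 by 0.10 ± 0.11 (-0.18 to 0.37) and Cd5 by -0.04 ± 0.14 (-0.38 to 0.29). Egr2 lay slightly lower with gp250, at -0.37 ± 0.09, which did not pass after adjustment (adjusted p = 0.716). Rag1 (0.08 ± 0.11), Rag2 (-0.18 ± 0.10), Bcl2l11 (0.07 ± 0.11) and Scn4b (0.36 ± 0.16, interval -0.04 to 0.75) did not pass either.

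In limma 0 of the 11942 probes passed an adjusted p of 0.05, and the smallest was 0.716. At an unadjusted p under 0.05 there were 782 probes, against 597.1 that chance would give. The largest difference at any probe was 1.01 on the log2 scale, and for 98.4% of probes the 95% interval lay inside a 2-fold change in either direction. Of the 2092 probes that MCC changed at least 2-fold, 2078 (99.3%) had such an interval for gp250 against Hb. Their median absolute log2 difference was 0.10 for gp250 against Hb and 1.48 for MCC against Hb. Some of these probes, such as those of Akr1c18, Cd160 and Srm, were below background on all gp250 and Hb arrays. At such probes, which also count in the 98.4%, an interval inside 2-fold is close to given. A gp250 change below background would not show there. None of the 22 lists was called by camera with a preset correlation, by camera with an estimated correlation or by fry, and 1, 0 and 0 had an unadjusted p under 0.05. No list member passed when adjusted over the list alone. Median, mean and test differed in sign for the negative selection, BCL2, cytokine, regulatory T cell, TCR signalling, channel and cholesterol lists, whose medians lay between -0.05 and 0.02. The cell cycle list had the smallest camera p, with 0 of 19 members passing, a median of -0.09 and an adjusted p of 0.328. Without gp250 replicate 2 its adjusted p was 0.0363, and without any other array it lay between 0.422 and 0.929. The simulated data used the moderated spread that the model shares between all ligands, MCC among them. There 94% of 2-fold changes, 60% of 1.5-fold changes and 12% of changes of 25% were recovered, all set on the normalized scale. Most changes of that last size were therefore not detectable with these arrays. For dim probes, whose fold changes the offset shrinks, recovery of a transcript change may be lower.

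**Figure D2:**
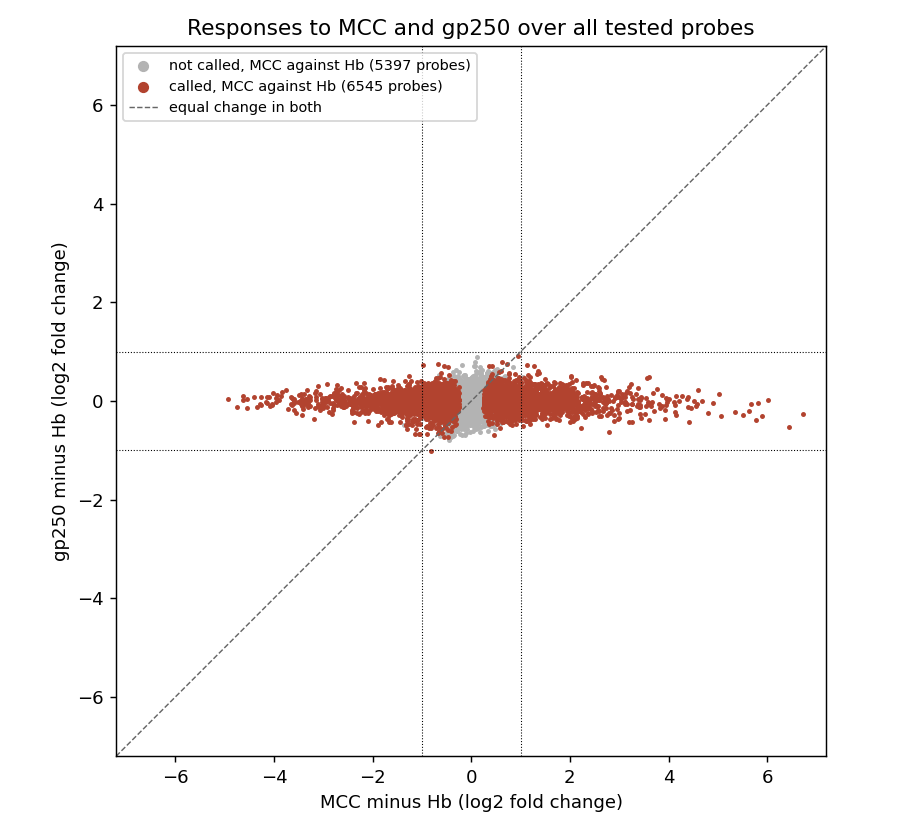
Each point is 1 of the 11942 tested probes, placed by its log2 fold change for MCC against Hb (horizontal axis) and gp250 against Hb (vertical axis); red points passed an adjusted p of 0.05 for MCC against Hb, grey points did not. Dotted lines mark 2-fold changes and the dashed line equal change. The points spread up to 6.73 horizontally and no further than 1.01 from 0 vertically.

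The comparison of MCC with gp250 sets the negative-selecting against the positive-selecting ligand directly. Its result was close to that against Hb: the 8 genes with the largest rises were the same 8, and 7 of the 8 with the largest falls were shared. Cldn10 was 127-fold higher with MCC than with gp250 (log2 6.98 ± 0.10), Egr2 71.3-fold higher (6.16 ± 0.09) and Itm2a 47.5-fold higher. Dntt was 26.3-fold lower, and B3gnt8, a glycosyltransferase gene, 18.6-fold lower. Against Hb a dimmer B3gnt8 probe changed less than this one (log2 -2.72, beside -4.13). Scn4b was at least 4.79-fold lower with MCC, and Bcl2l11 again did not pass on its brightest probe (log2 -0.10 ± 0.11, adjusted p = 0.492). Its dimmest tested probe had deposited signals of 76.8 and 134 with MCC against 49.8 and 42.9 with gp250. These are not scaled between arrays, and the array means were higher with MCC too. The fitted change of that probe against gp250 is not given here, so a rise of Bcl2l11 over gp250 on it stays open.

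In total 6658 probes passed (55.8%), 3242 up and 3416 down with MCC. Of these, 5924 also passed for MCC against Hb, 5923 in the same direction. Both comparisons use the MCC arrays, so these calls are not independent of each other. Groups simulated without any change shared 0 calls, but such groups give hardly any calls to share. The same 10 lists were called as against Hb, 9 up and 1 down, and again 0 with an estimated correlation, where 5 had an unadjusted p under 0.05; fry called 18. Without scaling between arrays 5023 of 6933 passing probes rose and 1910 fell, and the lists for maturation (adjusted p = 0.102) and negative selection (adjusted p = 0.0589) were not called. Their median log2 changes were not smaller there, at 2.21 against 1.83 for maturation and 1.65 against 1.42 for negative selection. Ribosome biogenesis had 16 of 17 members up (adjusted p = 9.97e-09; adjusted p = 0.148 with an estimated correlation). The genes of the stage before selection had 11 of 13 down (adjusted p = 0.000151; adjusted p = 0.181 with an estimated correlation), and both counts were equal when adjusted over the list alone. Median, mean and test differed in sign for the NF-kappaB, TCR signalling, interferon and myeloid lists, none of them called. Nfkbid, an NF-kappaB regulator, was among the members that rose (log2 2.01 ± 0.10), as was the chemokine gene Ccl3, at least 7.93-fold higher.

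**Figure D3:**
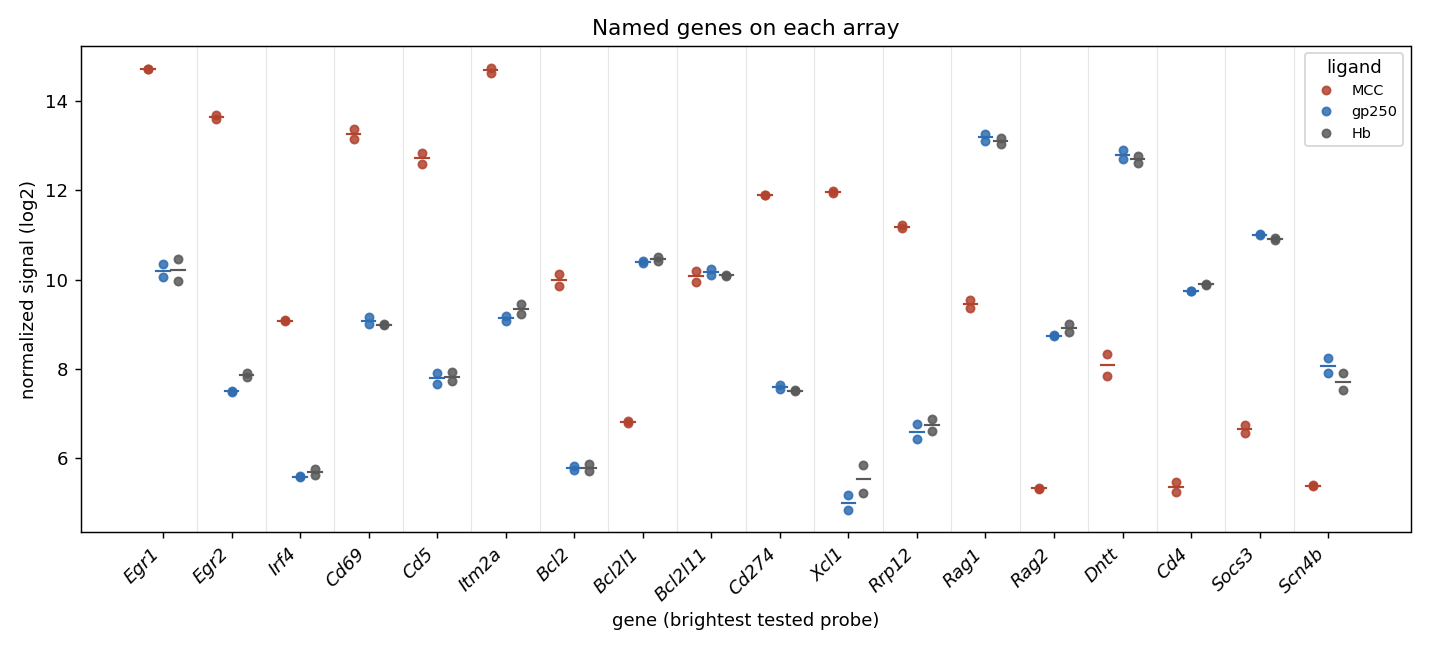
Normalized log2 signal of 18 named genes on each of the 6 arrays, by ligand, with points for arrays and short lines for group means. For Egr1 the MCC arrays averaged 14.72, the gp250 arrays 10.20 and the Hb arrays 10.21; for Rag1 the MCC arrays averaged 9.45 against 13.19 with gp250 and 13.11 with Hb; for Bcl2l11 the 3 means lay between 10.07 and 10.17.

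Whether the response to gp250 was a smaller version of that to MCC, or had genes of its own, was examined probe by probe. No probe was apart in gp250 alone, that is, higher or lower with gp250 than with both other ligands, and no probe was graded from Hb through gp250 to MCC, by limma at an adjusted p of 0.05 in both differences. At an unadjusted p under 0.05 in both differences there were 363 and 146 such probes. The single differences had 782 (gp250 against Hb) and 7269 (MCC against gp250) probes under it. Both differences use the gp250 arrays, so noise in those arrays alone would favour probes apart in gp250. No chance value was computed for the 2 counts, so they name no candidates. Across probes, which are not independent replicates, the MCC and gp250 responses against Hb correlated with r = 0.0381 and rho = 0.0569. Without Hb replicate 1 the correlation was 0.0940, without Hb replicate 2 it was 0.113 and without gp250 replicate 2 it was 0.0187. The shared Hb arrays alone gave r = 0.501 in simulated unchanged groups, with a covariance of 0.00998 against 0.00594 observed. MCC was unchanged in those groups too, while the observed MCC response had a variance of 0.827, so their r is no reference for the observed r. Only the covariances can be compared, and they differed by -0.00404. When each response was taken against a different Hb array, r was -0.0541 and -0.0272. The first principal component held 90.9% of the variance and separated the MCC arrays, at -66.5 and -66.1, from the others. The gp250 arrays lay at 34.0 and 33.4 and the Hb arrays at 32.9 and 32.3. On the second component, with 2.49% of the variance, the gp250 arrays lay at 14.4 and 1.76 and the Hb arrays at -6.57 and -9.82. The MCC arrays lay there at 2.40 and -2.18.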

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

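No scaling between arrays was chosen after the data were seen; the other alternatives were not. Over other background corrections, offsets, scalings, filters, variance models, fits to 4 arrays and the stricter threshold, 4643 to 7012 probes passed for MCC against Hb and 4787 to 7072 for MCC against gp250. None passed for gp250 against Hb, apart in gp250 alone or graded, under any alternative run. Requiring a 2-fold change left 2092 and 2132 probes, by its own construction. The number of lists called for each MCC comparison was 8 to 11, the lowest without scaling between arrays, except with an estimated correlation and with fry. Fry, which by construction compares no list with other genes, called 20 and 18. With an estimated correlation 0 and 0 were called, although the estimates lay on both sides of the preset 0.01. They were -0.0552 for ribosome biogenesis, -0.0668 for negative selection, 0.0113 for the immediate-early genes and 0.118 for glycolysis. The immediate-early list, with an estimate next to the preset, still went from an unadjusted camera p of 2.29e-07 to 0.0144 for MCC against Hb. For these genes, ribosome biogenesis and negative selection, the estimates argue against a correlation well above the preset as the reason. Their lost calls are therefore no sign of correlated genes. The cause was otherwise not tested. The correlation of the responses was 0.0706 without a filter and 0.00713 with the stricter filter; the cause was not tested. Leaving out each array in turn, where the lone array is assumed to vary like the others, gave 5275 to 6460 probes for MCC against Hb and 5388 to 6556 for MCC against gp250. The correlation then ran from 0.0187 to 0.113, and the lists called for gp250 against Hb from 0 to 1 (the cell cycle list). Differences between replicates 1 and 2 correlated across ligands at 0.0170, -0.00391 and -0.0228, so no shift shared by arrays of the same number was seen. What the number means is not said by the labels, and a shared origin is not excluded by this. With the number as a replicate block, 6331, 0 and 6474 probes passed and no other count of calls moved by over 1.5 times. Of 2044 alternative values of named genes, 2016 kept their side of the threshold, 28 lost it and 0 reversed. Those 28 belong to Krt8, Klf1, Cd79a, Hba-a1 and H2-Ab1, all changed by under 2-fold; other scalings ended calls of Krt8, Hba-a1, Cd79a and, for MCC against gp250, Klf1. Signal near background limits the genes given as bounds. Slide as a block was not run, since no slides are given.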

Other observations

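The tests in this part were chosen only after the results they bear on were seen, except the exchange of arrays. Further gene families were chosen after the data were seen and tested for MCC against Hb with camera, adjusted over 15 families. Of 16 cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs, 13 rose and 0 fell (adjusted p = 4.5e-05; adjusted p = 0.154 with an estimated correlation), with Aars 3.29-fold and Rars 3.10-fold higher. Among 35 translation initiation factors 18 rose and 4 fell (adjusted p = 0.00788; adjusted p = 0.154 with an estimated correlation), led by Eif5a at 2.75-fold. Subunits of RNA polymerases I and III had 6 up and 0 down of 10 (adjusted p = 0.00287; adjusted p = 0.154 with an estimated correlation), with Polr1a at 3.90-fold. The TCP1 chaperonin had 6 up and 0 down of 8 (adjusted p = 0.00397; adjusted p = 0.171 with an estimated correlation), and proteasome subunits 24 up and 2 down of 34 (adjusted p = 2.68e-05; adjusted p = 0.154 with an estimated correlation), with Psmd1 changed most, at 1.92-fold. Cytosolic ribosomal proteins did not follow: 9 of 57 rose and 6 fell (median -0.00, adjusted p = 0.726), and that median lay between -0.04 and 0.28 over 6 scalings, the highest without scaling between arrays, where the median of all probes was 0.22.

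Mitochondrial ribosomal proteins had 37 up and 5 down of 70 (adjusted p = 4.5e-05; adjusted p = 0.154 with an estimated correlation), with Mrps18b at 4.18-fold, and complex I of the respiratory chain 17 up and 1 down of 32 (adjusted p = 0.000921; adjusted p = 0.176 with an estimated correlation), the fall being that of Ndufa6 (log2 -1.02). In serine and one-carbon metabolism 6 of 8 rose and 2 fell (adjusted p = 0.00949; adjusted p = 0.154 with an estimated correlation), with Mthfd1 7.26-fold, Shmt2 5.82-fold and Psat1 5.43-fold higher. In purine and pyrimidine synthesis 10 of 13 rose and 1 fell (adjusted p = 0.0018; adjusted p = 0.154 with an estimated correlation). There Gart rose 3.24-fold while Impdh1, which opens the branch to guanine nucleotides, fell 3.43-fold. Cad, which changed most in this family (fitted log2 2.10), is also a member of the fixed ribosome biogenesis list. Circadian clock genes went both ways: Per1 (6.33-fold) and Per2 (6.20-fold) rose and 8 of 11 fell, among them Dbp by 2.01 on the log2 scale, but the family was not called (adjusted p = 0.0795). Histone genes (1 up and 3 down of 5, adjusted p = 0.323), claudins (1 up and 1 down of 5, adjusted p = 0.908), GIMAP GTPases (0 up and 2 down of 7, adjusted p = 0.71) and MHC class I genes (0 up and 1 down of 11, adjusted p = 0.71) were not called. Test directions of the 15 families held under 6 scalings, and so did the calls, except that the clock genes were called without scaling between arrays (adjusted p = 0.0231). There the medians of the GIMAP and MHC class I genes turned to 0.13 and 0.08, below the 0.22 of all probes. For gp250 against Hb camera called 0 families, with 1 at an unadjusted p under 0.05 and a smallest adjusted p of 0.364.

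The absence of any call between gp250 and Hb, from a ligand whose label names positive selection signals, is the pattern that most invites a closer look. An exchange of a gp250 and an Hb array would move a large difference to another split of the 4 arrays, but the other 2 splits called 0 probes, with 631 and 671 at an unadjusted p under 0.05 against 782. Too little precision for 2-fold changes is argued against by the 99.3% of MCC-responsive probes whose interval excludes them. This holds only for probes above background with gp250 or Hb, since below background such an interval is close to given. A weak form of the MCC response is argued against by the sign of a slope. Over 4 pairings of single arrays, gp250 minus Hb followed the MCC response with a mean slope of -1.03% (-1.63% to -0.433%). Within a ligand the slope was at most 0.637% in size. Too little precision for changes near 25% stays open, since 12% of simulated ones were recovered. A response that had passed by 7 h, or had not begun, may also account for it and was not tested, as only 1 time was measured.

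The breadth of the MCC response, 54.8% of the tested probes, could come from the quantile step between arrays or from other cells in the MCC cultures. The 3 settings without the quantile step, among them no scaling between arrays, each called at least 6502 probes, against 6545, which argues against the former for the count, though not for the share of rises among the calls (69.9% without scaling, 48.5% with the quantile step). Of the tested markers of other cell types 20% rose (H2-Ab1, Nkg7 and Krt8) while 7 of 15 fell, so these markers did not rise as a group. Over all 11942 tested probes, 3176 rose and 3369 fell. The 15 markers were pooled over 5 lists, and the rest of the 69 were not tested. More or fewer cells of a single other type in the MCC cultures can therefore not be excluded. Log2 signals with MCC and with Hb were 11.70 and 11.55 for Cst3, 11.22 and 11.75 for Hba-a1 and 11.15 and 11.91 for Prf1, which rank probes and not transcripts. A response of the thymocytes themselves stays a hypothesis that was not argued against, and so does a changed mix of cells.

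Bcl2l11 did not pass the test while Bcl2 rose, in cells given a ligand labelled for negative selection. A single failing Bcl2l11 probe is argued against by another detected probe (-0.04, 95% interval -0.27 to 0.20), beside -0.30 to 0.24 for the brightest. Whether a single Bcl2 probe misleads cannot be decided by its other probes. All 6 had fitted rises of 2.58 or more, which are not lower bounds, but 5 of these were detected on the MCC arrays alone. Those 5 passed the detection filter only through MCC, so a dim probe without a rise could not have entered. That Bcl2 transcripts rose at 7 h without a like rise of Bcl2l11 transcripts may be kept as a hypothesis, but a moderate rise of Bcl2l11 stays open, since its dimmest tested probe gave 0.48 (log2, 95% interval -0.05 to 1.02, adjusted p = 0.109). It does not extend to survival genes in general, since Bcl2l1 fell by 3.66 (log2). Protein levels and cell death were not measured here.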
